A study of Tetrahymena thermophila with 13 samples.

How the data were processed

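RNA of mating Tetrahymena thermophila was examined in 13 libraries, 1 per group: nuclear run-on RNA of a micronucleus-enriched fraction at 2 h, whole small RNA of wild type (WT), nulli4 and TWI1 knockout (KO) at 3 h and of WT at 8 h, and oxidised small RNA of WT and EMA1 KO at 3, 4.5, 6 and 8 h. Groups and times were taken from the labels. Per the labels' protocols, small RNAs were cut from a gel between size markers, with or without periodate oxidation, ligated to adapters and amplified, and the markers were cut with PmeI. Per the labels' protocols, the run-on RNA was made in isolated nuclei with a brominated nucleotide, hydrolysed and enriched with an antibody.

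The deposited files listed 1 read of 25 nt per line, with no count, position or other unit, and neither adapter removal, quality filter, aligner nor genome build is given in the sources used here. The run-on list held 50000001 lines, 6 of which were quality strings, and the round total makes a limit on its length possible to suspect but not to test. Reads with other letters than A, C, G and T were left out, as were reads with a size marker or adapter sequence with at most 2 mismatches and reads with 20 of 25 identical bases. The usable reads numbered 45598656 for run-on RNA. They numbered 16149418, 14021541, 18174243 and 19406137 for whole RNA of WT 3 h, nulli4, TWI1 KO and WT 8 h, 12143390, 14513327, 23293260 and 22286064 for oxidised WT and 19137972, 24920740, 22987431 and 23388315 for oxidised EMA1 KO at the 4 times in order.

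The comparisons planned before the data were examined needed a genome: shares of reads matching the somatic genome, reads per gene and per scaffold or window, gene lists, and the level of the targeted genes in the knockouts. No genome was used here, so these were not computed and the planned rule for naming genes could not be applied. Of the planned results, the recurring sequences and the opposite-strand overlaps were computed in a form that needs no genome, with contigs in place of genome positions and without the condition that a sequence lacks a genome match. The other measurements replaced the planned ones after the reads had been seen, and other k-mer lengths and minima for the assembly were explored before the settings given here were kept.

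Contigs were built from a de Bruijn graph of 21-mers over sequences with at least 2 pooled reads in at least 2 libraries of small RNA, in all 13644940 of 41202814 distinct sequences from 231671071 reads. A 21-mer with under 0.1 times the coverage of another that differed only in an end base was pruned and contigs of at least 60 nt were kept. The 56858 contigs had an N50 of 90 nt and a longest of 1320 nt. Reads were placed on them by exact match. The ratio of reads scaled to usable reads (RPM) was compared for contigs with at least 100 reads in both libraries together, with an exact binomial 95% interval. A contig was called lower or higher when the interval lay wholly below 0.5 or above 2. For log2 values 0.5 reads were added. Classes were lost (interval below 0.25), rising (above 2) and steady in WT whole RNA, 8 h over 3 h. Contigs depleted in nulli4 had at least 200 WT reads and a log2 ratio of -2 or lower.

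The sequences called kept in EMA1 KO were those starting with T with at least 20 reads in the EMA1 KO 4.5 and 6 h libraries together and a rate in WT at least 8-fold lower. Reads for conserved proteins were those encoding 8 residues in a row, on either strand and in any frame under genetic code 6, of 28 protein sequences written down from general knowledge of these families. The 13 proteins with at least 40 reads were named. The same proteins read backwards gave the chance level. Lists were set beside 10000 random contig lists matched to 0.8 to 1.25 times the reads. Opposite-strand pairs were counted for overlaps of 15 to 40 nt, with each distinct end counted once, and also for ends starting with A against ends starting with T. Recurring sequences had at least 5 reads in WT 3 h whole RNA. Shares have Wilson intervals.

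The calls were tested on simulated data with Poisson counting error only, so the result does not cover variation between cultures or libraries. For WT and EMA1 KO oxidised RNA, 8 h over 3 h, reads were drawn for 56858 contigs with 200 changed, and 100% of the contigs made 8-fold lower and 100% of those made 4-fold higher were called, while 0 of 22079 and 0 of 25074 unchanged contigs were. The peptide search found 100% of 1000 planted reads and 3 of 1000000 random ones, and a planted overlap of 27 nt was found. The assembly of 200 simulated loci gave 202 contigs, 100% of them exact. These loci were random sequence with reads at every position, a simpler case than the real reads. Alternatives changed the scaling, the read minimum, the contig length, the first base, the counting of distinct sequences and the rules for classes and sets. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.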

Results

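Mating Tetrahymena thermophila cells make a class of small RNAs from the germline nucleus, the micronucleus (Mic), while the somatic nucleus, the macronucleus (Mac), carries the expressed genome. The small RNAs are later used to mark DNA that is removed from the new somatic genome. The libraries asked how the small RNA population came to be biased, by transcription in the germline nucleus and by loss of RNAs afterwards. Small RNAs were sequenced in 12 libraries and nuclear run-on RNA in 1 library. The small RNA libraries came from wild-type (WT) pairs, from strains that lack germline chromosome 4 (nulli4), from cells without TWI1, which encodes the Argonaute protein that binds these small RNAs, and from cells without somatic EMA1, which encodes a putative RNA helicase that acts with it. WT and EMA1 knockout (KO) cells were taken at 3, 4.5, 6 and 8 h after mixing as oxidised RNA. Periodate oxidation leaves RNAs with a modified 3' end, the form bound by the Argonaute, able to enter a library. Whole RNA, not oxidised, was sequenced from WT at 3 and 8 h and from nulli4 and TWI1 KO at 3 h.

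Each group held 1 library, so no difference below has a replicate check, and a comparison of reads compares 2 libraries and not the conditions they stand for. All intervals are 95% intervals that cover counting error only. The small RNA libraries held from 12214018 reads in WT 3 h oxidised RNA to 24965882 reads in EMA1 KO 4.5 h oxidised RNA, each read 25 nt long. After removal of size marker, adapter and low-complexity reads, 12143390 to 24920740 reads per library were usable. The run-on list held 50000001 lines but only 737928 distinct sequences. No reference genome was used here. Loci were therefore represented by 56858 contigs joined from the reads themselves, with a total length of 5368689 nt and a median of 77 nt, and none has a genome position or gene annotation. From 24.9% to 32.5% of the usable reads of each small RNA library lay on them. The contigs, their classes, the sequence sets and the protein list were set up after the reads had been examined.

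Small RNAs of the oxidised libraries began almost without exception with T (U in the RNA), and those of the WT and TWI1 KO whole RNA libraries did so less often. The share of usable reads starting with T was 96.9% to 97.7% over the 8 oxidised libraries. It was 75.2% in WT 3 h whole RNA, 67.2% in TWI1 KO 3 h whole RNA and 87.5% in WT 8 h whole RNA, where A was the next most frequent first base at 17.0%, 22.0% and 6.80%. The nulli4 library, labelled as whole RNA, had 96.2% of reads starting with T and 2.06% starting with A. Reads with the sequence pattern of the 5' part of a tRNA and a first base other than T made up 1.48% of the TWI1 KO library, 0.849% of WT 8 h whole RNA, 0.458% of WT 3 h whole RNA, 0.109% of the nulli4 library and 0.0493% to 0.148% of the oxidised libraries. The run-on library had a different make-up, with 45.5% of reads starting with A and 26.6% with T. The Wilson interval of the WT 3 h whole RNA share of T was 75.18% to 75.22%, and the other first-base intervals of the small RNA libraries were of like width, so these differences exceed counting error.

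**Figure D1:**
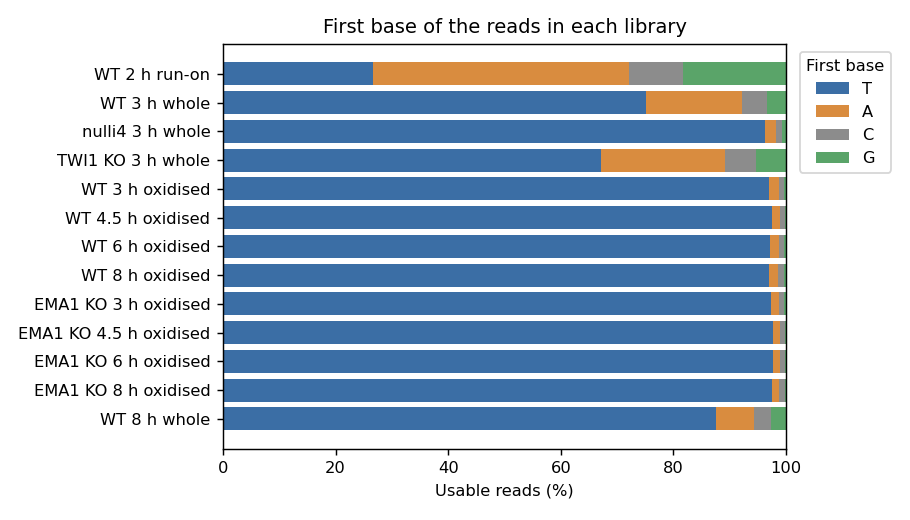
First base of the usable reads of each of the 13 libraries, as stacked percentages that start at 0. The share starting with T lies between 96.9% and 97.7% in the 8 oxidised libraries and at 96.2% in nulli4, above the 75.2%, 67.2% and 87.5% of the other whole RNA libraries.

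In WT, some loci lost most of their small RNAs between 3 h and 8 h while a larger number gained. Of 23223 contigs tested in oxidised RNA, 220 were lower at 8 h by more than 2-fold and 3651 were higher, by the rule that the whole counting interval lies beyond 2-fold, and 171 of the 220 had a log2 ratio below -2. Whole RNA of the same times gave 706 lower and 4205 higher of 21327 contigs. The whole RNA pair was then used to define 3 classes that could be followed in the oxidised libraries without choosing on them. Of this pair the 3 h library held reads with undetermined bases and the 8 h library none, so time and this processing difference go together in it. The 248 lost contigs had a ratio interval below 0.25, the 4205 rising contigs had an interval above 2, and 16874 others are called steady, among them the contigs called lower by more than 2-fold that missed the bound of the lost class. In oxidised WT RNA the median log2 ratio to 3 h of the lost contigs was -1.31 at 4.5 h, -2.63 at 6 h and -3.38 at 8 h, against -0.17 at 8 h for the steady contigs and 1.62 for the rising ones. With each distinct sequence counted once, the 8 h medians were -1.99 for the lost and 0.58 for the rising contigs. The lost contigs took 0.256% of the usable reads at 3 h (0.253% to 0.259%) and 0.0308% at 8 h (0.0301% to 0.0316%). The rising contigs went from 2.45% to 7.25%, and most of that gain was present at 4.5 h, when they held 6.03%. The rising contigs had a median GC content of 23.6%, the steady ones 26.9% and the lost ones 28.0%. With reads scaled to those placed on contigs, the higher count in oxidised RNA was 2314 and the lower count 248, and the median of the tested contigs moved by -0.20 on the log2 scale. With at least 10 reads, 2545 were lower and 4259 higher of 55228 contigs, so the share of higher calls was 62.6% in place of 94.3%. With each distinct sequence counted once, 13 contigs were lower and 2 higher.

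Reads that encode strongly conserved proteins, which mark gene sequence, declined over the same WT time course. A list of 28 proteins in 9 groups was searched for reads encoding 8 consecutive residues, and a match can come from any member of a protein family. Reads for Hsp90, a chaperone, went from 136 at 3 h to 22, 15 and 21 at 4.5, 6 and 8 h, a ratio of 0.0840 at 8 h relative to the reads starting with T (0.0504 to 0.134). Ubiquitin, the tag for protein degradation, went from 58 reads to 10, a ratio of 0.0938 (0.0427 to 0.185). Histone H3, a core chromatin protein, went from 24 reads to 4, a ratio of 0.0907 (0.0229 to 0.264). Hsp70, another chaperone, had a ratio of 0.312 (0.194 to 0.495), and beta-tubulin, a microtubule subunit, 0.453 (0.213 to 0.953). These were the 5 of 13 proteins with at least 40 reads whose interval lay below 1, none lay above 1, and the intervals were not adjusted for the number of proteins. The other 8 had between 0 and 11 reads in either library, so changes of several fold were not detectable for them. By group at 8 h over 3 h, the chaperones had a ratio of 0.149 (0.107 to 0.203), the ubiquitin group 0.0907 (0.0414 to 0.179), the histones 0.167 (0.0655 to 0.381) and metabolic enzymes 0.326 (0.0975 to 0.991). Tubulins (0.622), signalling proteins (0.789), translation factors (0.510) and ribosomal proteins (1.09) had intervals that held 1, and the actin group had 0 reads at 3 h and 4 at 8 h. In whole RNA the 8 h over 3 h ratio was 0.138 (0.0895 to 0.207) for Hsp90, 0.170 (0.105 to 0.265) for ubiquitin and 0.221 (0.129 to 0.365) for Hsp70, while alpha-tubulin went from 1 to 36 reads, a ratio of 25.7 (4.33 to 1045). WT 8 h whole RNA also differed from 3 h in its share of reads with a conserved rRNA segment, 0.0154% against 0.000396%, and in the coding-strand share of its T-first protein reads, 72.0% against 38.6%. All listed proteins together in oxidised RNA went from 345 to 152 reads, a ratio of 0.240 (0.197 to 0.291), which is -2.06 on the log2 scale and was -1.07 with each distinct sequence counted once. Without ubiquitin, Hsp70 and Hsp90 it was 0.505 (0.375 to 0.680), and the same proteins read backwards gave 8 and 10 reads. Among 10000 random lists of contigs with like read numbers, 5.85% had a median as low as that of the 13 proteins, -1.18 on the log2 scale.

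**Figure D2:**
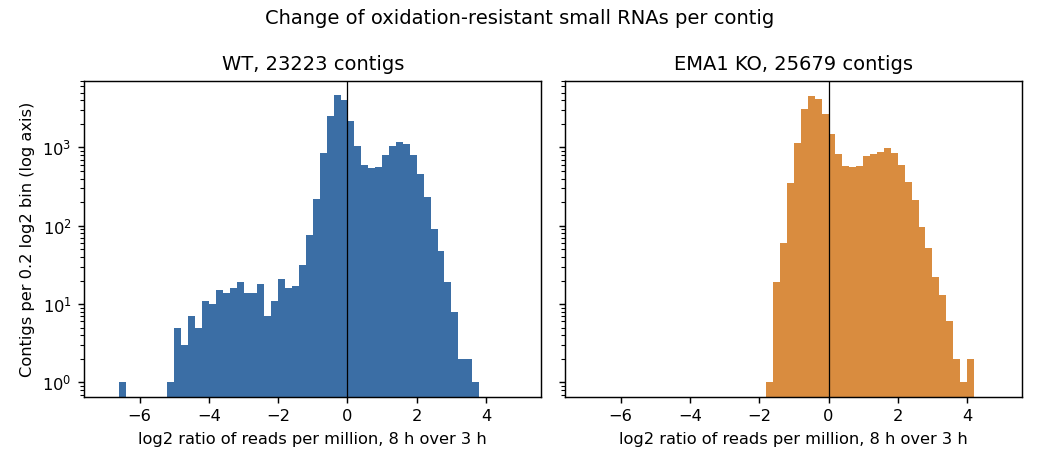
Number of contigs (log axis) by log2 ratio of RPM (scaled to usable reads) in oxidised RNA, 8 h over 3 h, in bins of 0.2, for WT (23223 contigs) and EMA1 KO (25679 contigs). Both strains have a second mode above 1, and the tail below -2 appears in the WT panel, where 171 contigs called lower lie below -2, and in no contig called lower in EMA1 KO.

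Without somatic EMA1, the loci that lost their small RNAs in WT kept most of them, and the loci that gained in WT still gained. The lost contigs had median log2 ratios to 3 h of -0.40, -0.47 and -0.45 at 4.5, 6 and 8 h in EMA1 KO, close to the -0.35 of the steady contigs at 8 h. They held 0.268% of the usable reads at 3 h and 0.199% at 8 h. The ratio between strains on these contigs grew with time, with a median log2 of EMA1 KO over WT of 0.07, 1.02, 2.20 and 3.02 at 3, 4.5, 6 and 8 h. With each distinct sequence counted once, the 8 h value was 1.4. Across all contigs, 6 of 25679 were lower and 3964 were higher at 8 h than at 3 h in EMA1 KO. At a minimum of 10 reads, 45 were lower and 5038 higher. With each distinct sequence counted once, 0 were lower and 1 higher of 4453 contigs tested. Of 20084 contigs tested in both time courses, 218 were lower in WT, 5 in EMA1 KO and 1 in both, where independent lists would share 0.0543. The contigs lower in WT had a median log2 ratio of -2.98 there and -0.47 in EMA1 KO. Of the 3297 higher in WT, 2476 or 75.1% were also higher in EMA1 KO, against 566 for independent lists, and the time courses share no library. Across the contigs tested in both, the log2 ratios of the strains had a Pearson r of 0.852 and a Spearman rho of 0.744, and contigs are not independent replicates. The rising contigs had a median log2 ratio of 1.67 at 8 h in EMA1 KO and 1.62 in WT. Over the 4 times, the median log2 difference on the lost contigs averaged 1.58 and was above 0 at 4 of 4 times. An exact two-sided sign-flip permutation test over the 4 time pairs gave p = 0.12, the smallest it can give with 4 pairs, so this test cannot reach 0.05. The 4 times are also not independent replicates of the strain difference, so this p does not measure variation between cultures.

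Conserved protein reads stayed at their 3 h level in EMA1 KO. All listed proteins had 676, 952, 774 and 778 reads at 3, 4.5, 6 and 8 h, and the 8 h over 3 h ratio was 0.940 (0.847 to 1.04). Ubiquitin had a ratio of 1.04 (0.857 to 1.27) and Hsp70 0.962 (0.764 to 1.21), while histone H3 at 0.440 (0.246 to 0.766) and Hsp90 at 0.809 (0.661 to 0.989) had intervals below 1. All listed proteins together, which needed no read minimum, had a log2 ratio of EMA1 KO over WT of 2.28 at 8 h. At 8 h the interval of EMA1 KO over WT lay above 1 for 7 of the 13 proteins and below 1 for 0, while 2 had a ratio below 1. The read minimum that chose the 13 was not shown to be independent of the EMA1 KO libraries. It may favour proteins with many reads there, so the split of 7 to 0 can come in part from that choice. The 7 included ubiquitin at 22.2-fold (11.9 to 46.9), Hsp90 at 8.94-fold (5.69 to 14.8) and the vesicle traffic protein Rab1 at 5.93-fold (2.05 to 23.4). The others were the translation factor eIF4A at 5.69-fold (1.27 to 52.4), Hsp70 at 5.08-fold (3.45 to 7.72), histone H3 at 4.98-fold (1.68 to 20.0) and beta-tubulin at 2.34-fold (1.3 to 4.6). Calmodulin, a calcium sensor, had a ratio of 0.776 (0.284 to 2.06) and elongation factor 1-alpha 1.07 (0.365 to 3.18). At 3 h the strains were closer, with a ratio of 1.24 (1.09 to 1.41) for all listed proteins, 1.99 (1.48 to 2.73) for ubiquitin and 0.929 (0.744 to 1.16) for Hsp90. Without ubiquitin, Hsp70 and Hsp90 the 3 h ratio was 0.990 (0.763 to 1.29) and the 8 h ratio 1.90 (1.47 to 2.47). The mean log2 difference over the 4 times was 1.57, above 0 at 4 of 4 times, again with p = 0.12 in the exact sign-flip permutation test. The limits of that test given above apply here too. The 13 proteins' median lay at percentile 87.0 of 10000 matched random contig lists for EMA1 KO 8 h over 3 h.

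**Figure D3:**
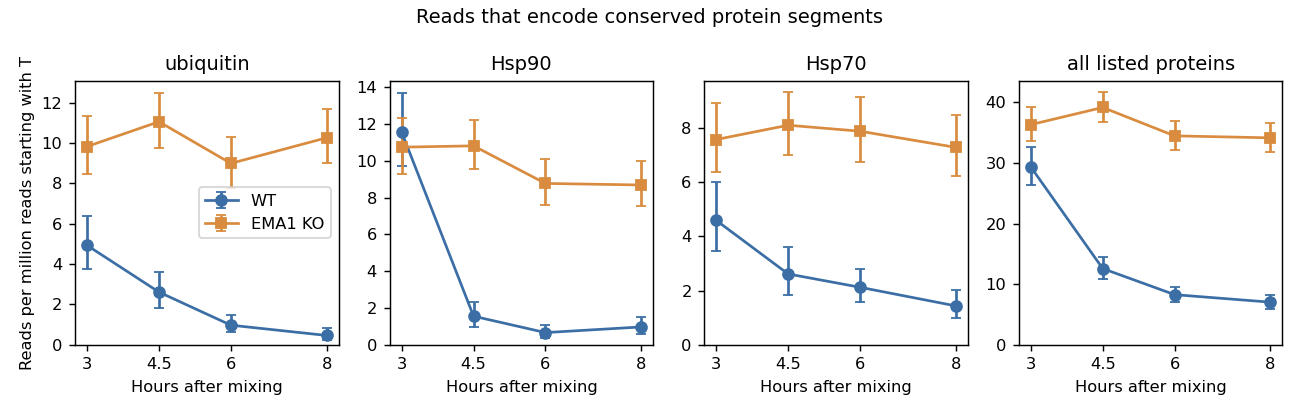
Reads encoding 8 residues of ubiquitin, Hsp90, Hsp70 and all listed proteins as RPM of the reads starting with T, against hours after mixing, in oxidised RNA of WT and EMA1 KO. Bars are 95% Poisson intervals of counting error for 1 library per point, and the all-protein level goes from 29.3 to 7.03 in WT and from 36.3 to 34.1 in EMA1 KO.

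Sequences that were present in EMA1 KO and nearly gone from WT at 4.5 and 6 h were also plentiful in early WT whole RNA. Of 315165 T-first sequences with at least 20 reads in the EMA1 KO 4.5 and 6 h libraries, 13527 had a rate in WT at least 8-fold lower. The 4.5 and 6 h libraries chose this set, and no other library entered the choice. A lasting difference between the strains or cultures would still carry over to 3 and 8 h. The share at 3 h was already 2.24-fold higher in EMA1 KO than in WT oxidised RNA. The set made up 1.67% of T-first reads in EMA1 KO at 3 h and 1.48% at 8 h. In oxidised WT RNA it made up 0.747% at 3 h (0.742% to 0.752%) and 0.0563% at 8 h (0.0553% to 0.0573%), so that the 8 h share was 26.3-fold higher in EMA1 KO than in WT. In WT whole RNA it went from 1.42% at 3 h to 0.248% at 8 h. The log2 ratio of WT 8 h over 3 h in oxidised RNA was -3.73, and it was -2.01 with a minimum of 5 reads and -2.47 with a 4-fold rule for the rate in WT. Under the 4-fold rule the EMA1 KO value changed sign from -0.18 to 0.016. TWI1 KO whole RNA at 3 h held 1.51%, close to WT whole RNA, and the nulli4 library held 0.481%.

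**Figure D4:**
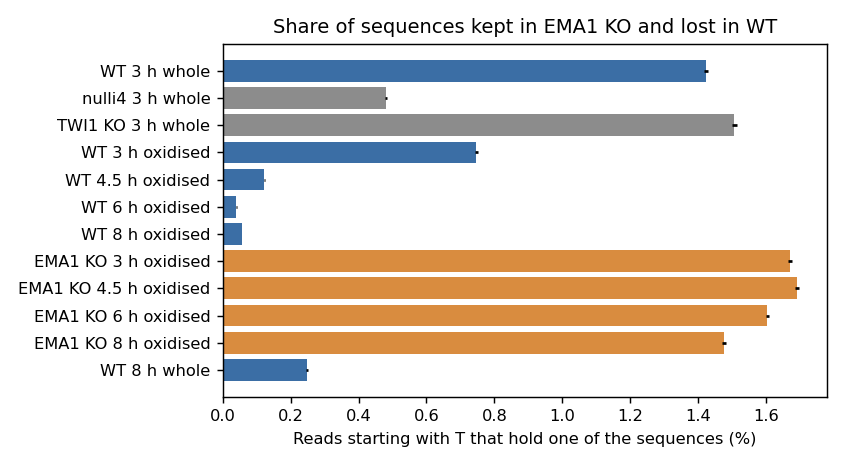
Share of reads starting with T that hold 1 of the 13527 sequences kept in EMA1 KO and lost in WT, for each small RNA library, with Wilson 95% intervals of counting error. The EMA1 KO bars lie between 1.48% and 1.69%, and the oxidised WT bars between 0.0399% and 0.747%.

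More contigs were called different between EMA1 KO and WT at the later times, when WT depth was greater and 27530 contigs were tested in place of 19779. The quartiles of the log2 ratio were -0.62 and 0.34 at 3 h and -0.80 and 0.23 at 8 h. EMA1 KO was lower at 471 contigs and higher at 70 at 3 h, lower at 1030 and higher at 421 at 4.5 h, lower at 1680 and higher at 576 at 6 h, and lower at 1893 and higher at 759 at 8 h. The excess of lower contigs depends on the scaling and on the read minimum. Scaled to the reads placed on contigs, the counts were 172 lower and 181 higher at 3 h, 388 and 712 at 4.5 h, 531 and 934 at 6 h, and 682 and 1090 at 8 h. That scaling moved the median of the tested contigs by 0.17, 0.20, 0.27 and 0.26 on the log2 scale. With at least 10 reads the counts were 2189 lower and 2727 higher at 6 h, and 2582 and 3588 at 8 h. The EMA1 KO libraries and WT 8 h whole RNA held no reads with undetermined bases while every other library did, so strain and this processing difference go together in the oxidised libraries.

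At 3 h, oxidised WT RNA was richer than whole RNA in the contigs that rose with time. The rising contigs had a median log2 ratio of oxidised over whole RNA of 0.92, with 96.1% above 0, but they were chosen with the same WT 3 h whole RNA library, so this value is not independent of the choice. The 3964 contigs rising in EMA1 KO, which were chosen with neither library, lay 0.84 above the others at 3 h and at -0.18 relative to them at 8 h. Few contigs passed the 2-fold rule. At 3 h, 39 of 17513 contigs were lower and 144 higher in oxidised than in whole RNA, and at 8 h 87 of 25386 were lower and 69 higher. Scaled to the reads placed on contigs, the 8 h counts were 164 lower and 10 higher, and the 3 h counts 60 and 97. The sequences kept in EMA1 KO had a whole over oxidised ratio in WT of 1.91 at 3 h and 4.41 at 8 h. They were chosen for a low rate in oxidised WT RNA at 4.5 and 6 h. Ratios above 1 can therefore come from the choice and do not show an effect of oxidation. Conserved protein reads starting with T had an oxidised over whole ratio of 0.871 (0.752 to 1.0071) at 3 h and 0.515 (0.417 to 0.634) at 8 h. At 8 h, ubiquitin had a ratio of 0.314 (0.135 to 0.677), alpha-tubulin 0.196 (0.0832 to 0.415), elongation factor 1-alpha 0.37 (0.138 to 0.904) and the ribosomal proteins 0.105 (0.0268 to 0.297), while Hsp70 had 1.16 (0.645 to 2.12). Of the protein-coding reads with another first base, 989 of 999 in WT 8 h whole RNA were on the coding strand (99.0%, 98.2% to 99.5%), against 104 of 147 in WT 3 h whole RNA (70.7%, 62.9% to 77.5%). The coding-strand excess was not particular to whole RNA, with 53 of 53 such reads in WT 8 h oxidised RNA, 43 of 45 at 6 h, 6 of 11 at 4.5 h and 9 of 17 at 3 h.

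TWI1 KO RNA at 3 h was richer than WT whole RNA in the contigs that rose with time, and few contigs differed by more than 2-fold. Of 20301 contigs, 4 were lower and 66 higher in TWI1 KO than in WT whole RNA, and the median log2 ratio was 0.00 with quartiles of -0.23 and 0.25. The lost contigs had a median log2 ratio of -0.16 and the rising contigs of 0.77, with 95.9% of the rising contigs above 0, and the rising contigs held 2.29% of usable reads in TWI1 KO against 1.41% in WT. The classes were chosen with the same WT 3 h whole RNA library, so these class medians are not independent of the choice. The contigs rising in EMA1 KO, chosen without that library, lay 0.82 above the others in TWI1 KO over WT on the log2 scale. Over the same WT library they lay 0.65 above the others in nulli4 and 0.84 in WT 3 h oxidised RNA. The shift was therefore not particular to TWI1 KO. All listed proteins had a ratio of 1.09 (0.949 to 1.2), with Hsp90 at 1.43 (1.16 to 1.78), Hsp70 at 0.644 (0.430 to 0.954) and ubiquitin at 0.976 (0.736 to 1.29). Whether TWI1 and EMA1 themselves were missing from the KO libraries could not be checked without a gene annotation.

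Strains without germline chromosome 4 had few small RNAs from a group of loci. Their somatic nucleus still carries the chromosome 4 sequence, so the comparison asks which small RNAs depended on the germline copy. Of 17629 contigs tested by the general rule, 2191 were lower and 1029 higher in nulli4 than in WT 3 h whole RNA. With at least 10 reads, 7793 were lower and 2207 higher of 54357. With each distinct sequence counted once, 241 were lower and 1 higher of 4054. Of 3645 contigs with at least 200 reads in WT 3 h whole RNA, 486 (13.3%, and 13.0% of the tested length) had a log2 ratio of nulli4 over WT of -2 or lower. At a log2 ratio of -1 the depleted share of the length was 27%. The median log2 ratio of the 486 was -5.60, and that of the other contigs was -0.11. The nulli4 library had 8265 reads on the depleted contigs and WT had 198899, and 9 of the tested contigs had 0 reads in nulli4. The same contigs had a median log2 ratio of -0.03 in TWI1 KO over WT, with 0 of 486 at or below -2. In EMA1 KO over WT at 3 h their median was -0.92, against -0.20 for the other contigs, with 1 at or below -2. Against WT oxidised RNA the depleted share of the length was 13.8%, and 97.1% of the depleted contigs tested in both were depleted in both. Among conserved proteins, Hsp90 at 0.336 (0.243 to 0.460), ubiquitin at 0.403 (0.279 to 0.574) and calmodulin at 0.150 (0.0163 to 0.674) had ratios with intervals below 1 against WT whole RNA, and Hsp70 had 0.940 (0.664 to 1.33). Against WT oxidised RNA the ratio was 0.359 (0.258 to 0.494) for Hsp90 and 0.707 (0.471 to 1.06) for ubiquitin. Histone H3 and the metabolic enzyme GAPDH, with 13 against 24 reads and 1 against 8 reads, also had intervals below 1. The phosphatase PP2A had 7 reads against 0, an interval above 1, and the proteins read backwards had 22 reads against 8. Of the lost contigs 33.8% (24.2% to 44.9%) were depleted in nulli4, of the steady ones 13.2% (12.1% to 14.4%) and of the rising ones 7.03% (4.15% to 11.7%), but the WT 3 h whole RNA library entered both the classes and this depletion, so these shares are not independent of the choice. Against WT oxidised RNA, a library not used to choose the classes, the shares were 25.8% (13.7% to 43.2%), 14% (12.6% to 15.4%) and 11.7% (8.30% to 16.4%), and the intervals overlapped.

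**Figure D5:**
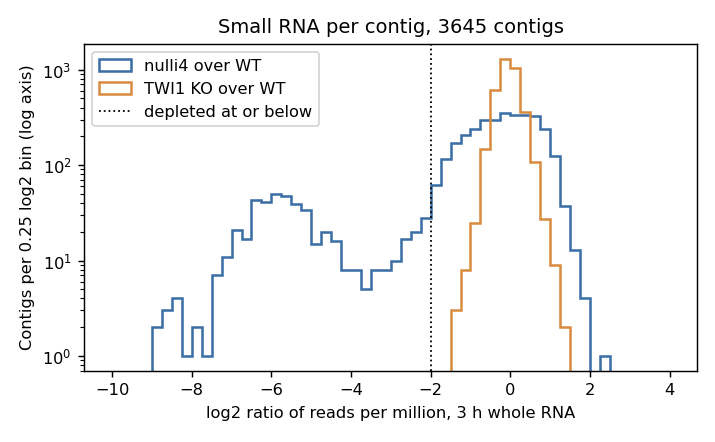
Number of contigs (log axis) by log2 ratio of RPM over WT in 3 h whole RNA, for nulli4 and for TWI1 KO, in bins of 0.25 over the 3645 contigs with at least 200 WT reads. The dotted line marks -2, and 486 contigs lie at or below it for nulli4.

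Run-on RNA of a nuclear fraction enriched for germline nuclei from WT at 2 h shared a small part of its distinct sequences, and a larger part of its reads, with the small RNAs. Of 727475 usable distinct run-on sequences, 6.28% (6.22% to 6.34%) were found on the same strand among the small RNAs of any library and 3.16% (3.12% to 3.2%) on the opposite strand. These sequences made up 44.6% and 10.9% of the run-on reads. A single small RNA read sufficed for such a match. For small RNAs with at least 10 pooled reads, the shares of distinct sequences were 0.897% on the same and 0.374% on the opposite strand. The shares of run-on reads were then 29.4% and 0.965%. On contigs there were 3729 distinct run-on sequences. The lost contigs had 4.53 of them per kb (3.85 to 5.30), the rising contigs 0.899 (0.825 to 0.979) and the steady contigs 0.715 (0.679 to 0.752). These intervals treat each distinct sequence as independent, but sequences on the same contig can overlap, so the intervals are too narrow. A run-on read lay on 20.6% of the lost, 7.09% of the steady and 2.40% of the rising contigs, so rising and steady contigs stood in the opposite order by this measure. Across contigs within this pair of libraries, log2 run-on reads had a Pearson r of 0.168 and a Spearman rho of 0.134 with TWI1 KO small RNA reads. Contigs are not independent replicates. Only 2158 contigs (3.80%) held a run-on read, and 10 contigs held 92.8% of the run-on reads on contigs. Most run-on values were therefore 0, and the low correlation cannot tell a weak relation from sparse sampling. The leading contig held 61.7% of the run-on reads on contigs, and each distinct run-on sequence was read 62.7 times on average. The values per kb therefore count distinct sequences, while these correlations use reads. With distinct sequences per nt the Spearman rho was 0.128.

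Opposite-strand small RNAs most often overlapped by 27 nt, measured from 5' end to 5' end, for ends with any first base. With each distinct end counted once, this length had the most pairs in every small RNA library but WT 3 h oxidised RNA, where 28 nt led with 1.32 times the median of the other lengths against 1.31 at 27 nt. The leading length stood 1.4 times above that median in WT 3 h whole RNA and TWI1 KO, 1.38 times in nulli4 and 1.24 times in WT 8 h oxidised RNA. For ends starting with A against ends starting with T, 31 nt led in oxidised RNA of WT at 4.5, 6 and 8 h and of EMA1 KO at 6 and 8 h, with 1.17 times the median against 1.06 at 27 nt in WT 8 h, and 28 nt led in WT 3 h oxidised RNA. Run-on sequences had their most frequent overlap at 25 nt, with 1.13 times the median.

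Sequences that recurred in WT 3 h whole RNA were found again in TWI1 KO more often than in nulli4 or after oxidation. Of 511906 sequences with at least 5 reads there, 2.86% were not seen in TWI1 KO, 18.4% not in WT 3 h oxidised RNA and 27.9% not in nulli4. With at least 20 reads, 71352 sequences remained and the shares were 0.00561%, 6.12% and 10.6%. Depth limits these shares, since the libraries differ in their number of usable reads, but it does not order them. Nulli4 had 14021541 usable reads and WT 3 h oxidised RNA 12143390. The set held sequences of any first base. Reads starting with T made up 96.2% in nulli4 and 96.9% in WT 3 h oxidised RNA, against 75.2% in WT 3 h whole RNA.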

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

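The tests in this part were chosen after the results were seen, except those of the first base and of GC content in the last paragraph.

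Size marker or adapter sequence made up 3.4% of the nulli4 reads and 8.59% of the run-on reads, which stood apart because such reads lie outside the measurement and made up 0.122% to 0.565% of the other libraries. The change in conserved protein reads differed between strains, with an 8 h over 3 h ratio 3.92-fold higher in EMA1 KO than in WT (3.16 to 4.87). On the lost contigs the same ratio of ratios was 6.17 (5.99 to 6.35). Both intervals cover counting error in 4 libraries and not variation between cultures.

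Small RNAs of the lost contigs fell further in WT than in EMA1 KO, where their median log2 ratio of -0.45 was close to the -0.35 of the steady contigs. A scaling to library totals would shift lost and steady contigs alike, but the contrast of lost minus steady contigs, WT minus EMA1 KO, was -3.11 on the log2 scale. A processing batch that lacks undetermined bases and keeps these contigs high would leave WT 8 h whole RNA without the loss. Lost contigs chosen in oxidised RNA lay at -3.03 relative to steady ones there, which argues against that form of batch only. The 3 h library of that pair held undetermined bases, so batch and time go together in it. Every oxidised WT library held them too, so another batch effect on the strain contrast is not excluded. The strain difference was 0.28 at 3 h and 3.4 at 8 h, and this growth of 3.11 restates the same contrast, so it is no separate test of a loss that needs EMA1. With 1 library per strain and time, a need for EMA1 cannot be told apart from another difference between the cultures.

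The nulli4 library, labelled as whole RNA, had the first bases of an oxidised library. Absence of chromosome 4 would leave other loci with the WT share of reads not starting with T. On contigs not depleted in nulli4 this share was 2.05%, against 24.1% in WT whole RNA of the same time label, 3 h. It was 4.73% in WT 8 h whole RNA and 1.73% to 2.26% in the oxidised libraries. A low share on these contigs therefore also occurred without oxidation, at 8 h. A later stage would raise the share on rising contigs to that of WT at 4.5 h, 6.03%, but it was 2.24%. The tRNA 5' pattern made up 0.0345% of T-first reads in nulli4, within the 0.0318% to 0.0521% of the oxidised libraries and below the 0.0948% to 0.135% of the other whole RNA libraries. The chance level from reverse complements was 0.0396% in nulli4 and 0.0323% to 0.0431% in the oxidised libraries, so the match is between values near chance, and it sets nulli4 apart from the other whole RNA libraries only. RNA that went through an oxidation-like selection is a candidate explanation, and a wrong label and a different RNA preparation stay open.

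Contigs that rose with time were low in WT 3 h whole RNA relative to the other 3 h libraries. The difference of TWI1 KO over WT on contigs rising in EMA1 KO stayed at 0.92 with T-first reads and at 0.81 within GC bins, which argues against first base and GC content. An earlier stage of mating in WT 3 h whole RNA predicts a larger share of the sequences kept in EMA1 KO, which fell with time in WT, and the whole over oxidised ratio of 1.91 at 3 h lay above 1 but below the 4.41 found at 8 h for the pair with the same time label. This cannot be told apart from the effect of oxidation itself, or from the choice of the set for a low rate in oxidised WT RNA. Whether the 8 h pair was at the same stage was not tested. The comparisons that show the pattern share the WT 3 h whole RNA library.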

How the results depend on the processing

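The alternatives were chosen after the data were seen, except the minimum of 20 reads for recurring sequences and the other ways of counting overlaps, which were set before. The mismatch, denominator, window, multiple-position and genome-scaling settings set before were not run because no genome was used here. Each group held 1 library, so no replicate number could serve as a block, and EMA1 KO was paired with WT by time in the exact sign-flip test. Of 213 alternative values of 53 results, 90 stayed within their tolerance, 120 moved, and 3 changed sign where the main interval excluded no change. A further 4 changed sign where it did not, for conserved protein reads: EMA1 KO 8 h over 3 h with distinct sequences, and TWI1 KO over WT with distinct sequences, with any first base (-0.0016) and without ubiquitin, Hsp70 and Hsp90 (-0.041). Of the 110 values that are counts of contigs, 38 stayed within 1.5 times. Unless stated, the cause was not tested. Depth limits the calls on contigs with few reads and the proteins with few reads.

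Scaled to reads placed on contigs, the higher count of WT oxidised 8 h over 3 h was 2314 and the lower count of EMA1 KO was 16. EMA1 KO over WT gave 172 lower and 181 higher at 3 h, 388 and 712 at 4.5 h, 531 and 934 at 6 h, and 682 lower at 8 h. Oxidised over whole gave 60 lower at 3 h, and 164 lower and 10 higher at 8 h. Lost contigs had medians of -3.58 in WT, -0.57 in EMA1 KO and 3.27 in EMA1 KO over WT at 8 h, and rising contigs 1.41, 1.55 and -0.12.

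With at least 10 reads, which tests more contigs, 2545 were lower and 4259 higher in WT and 45 were lower in EMA1 KO at 8 h over 3 h. EMA1 KO over WT gave 819 lower and 263 higher at 3 h, 1495 and 1192 at 4.5 h, 2189 and 2727 at 6 h, and 2582 and 3588 at 8 h, so that higher calls outnumbered lower ones at 6 and 8 h. WT whole gave 3675 lower and 7097 higher, oxidised over whole 90 and 606 at 3 h and 264 and 110 at 8 h, TWI1 KO over WT 18 and 198, and nulli4 over WT 7793 and 2207.

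With each distinct sequence counted once, which tests fewer contigs, 13 were lower and 2 higher in WT and 0 and 1 in EMA1 KO. EMA1 KO over WT gave 0 and 0 at 3 h and 1 and 0 at 4.5 h. That comparison gave 0 and 2 at 6 h, and 1 and 6 at 8 h. WT whole gave 42 and 72, oxidised over whole 0 and 2 at 3 h and 1 and 0 at 8 h, TWI1 KO 0 and 0, and nulli4 241 and 1. Lost medians were -1.99, -0.20 and 1.4 and rising medians 0.58, 0.69 and -0.42, in the order above. Conserved protein reads had log2 ratios of -1.07 in WT, 0.083 in EMA1 KO, 1.48 in EMA1 KO over WT at 8 h and -0.18 in TWI1 KO over WT, and the run-on correlation was 0.159.

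With contigs of at least 100 nt, which tests fewer contigs, 2258 were higher in WT, and 0 lower and 2376 higher in EMA1 KO. EMA1 KO over WT gave 297 lower and 27 higher, 572 and 196, 933 and 315, and 1031 and 391 at the 4 times. WT whole gave 346 and 2662, oxidised over whole 10 lower at 3 h and 20 and 13 at 8 h, TWI1 KO 0 lower, and nulli4 1374 and 573. The rising median in EMA1 KO was 1.69 and the run-on correlation 0.203.

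With reads starting with T, WT whole had 429 contigs lower and oxidised over whole 32 higher at 8 h, the rising medians were 1.64 in WT and 1.7 in EMA1 KO, and the leading overlap in WT 3 h oxidised RNA was 27 nt in place of 28 nt. With classes from the ratio without its interval, the lost medians were -3.04 in WT and 2.74 in EMA1 KO over WT, and the rising medians 1.55 in WT and 1.58 in EMA1 KO. With classes from oxidised WT, the EMA1 KO medians were -0.51 for lost and 1.71 for rising contigs.

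For the sequences kept in EMA1 KO, the log2 ratios of WT 8 h over 3 h, EMA1 KO 8 h over 3 h and TWI1 KO over WT were -3.73, -0.18 and 0.082. They were -2.01, -0.13 and 0.051 with at least 5 reads, -2.64, -0.14 and 0.061 with at least 8, and -3.05, -0.15 and 0.067 with at least 12. With a 4-fold lower rate in WT they were -2.47, 0.016 and 0.039, so the EMA1 KO value changed sign. With any first base the EMA1 KO value was -0.17 and the TWI1 KO value changed sign to -0.061.

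Conserved protein reads with any first base had log2 ratios of -1.70 in WT 8 h over 3 h and 1.93 in EMA1 KO over WT at 8 h. Without ubiquitin, Hsp70 and Hsp90 these were -0.99 and 0.92, and EMA1 KO over WT at 3 h changed sign from 0.31 to -0.014. The depleted share of contig length in nulli4 was 27% at a log2 ratio of -1. Recurring sequences with at least 20 reads were not seen in 10.6% for nulli4, 0.00561% for TWI1 KO and 6.12% for WT oxidised RNA.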

Other observations

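The tests in this part were all chosen after the reads were seen. The contigs depleted in nulli4 had a median log2 ratio of EMA1 KO over WT at 3 h of -0.92, against -0.20 for the other contigs. The nulli4 and EMA1 KO comparisons share no library, but each divides by a WT library of 3 h. Whether the EMA1 KO cells carry all of germline chromosome 4 could not be checked here. Across 7807 contigs, the log2 ratio of nulli4 over WT whole RNA and that of EMA1 KO over WT oxidised RNA had a Spearman rho of 0.361 and a Pearson r of 0.404, and contigs are not independent replicates.

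The strand of conserved protein reads starting with T shifted with time in WT. In oxidised WT RNA, 32.8% lay on the coding strand at 3 h (28.0% to 37.9%) and 56.6% at 8 h (48.6% to 64.2%). In EMA1 KO the shares were 39.1% (35.4% to 42.8%) and 48.8% (45.3% to 52.4%). In WT 8 h whole RNA the share was 72.0% (65.9% to 77.4%). The difference between strains in this shift was not tested.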
